A study of Caenorhabditis elegans with 2 samples.

How the data were processed

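The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) from whole Caenorhabditis elegans at the fourth larval stage, 47 hours old, after synchronisation by starvation of hatchlings. The strain carries a transgene with the gene daf-8 fused to a green fluorescent protein tag, and the tag was precipitated with an antibody against that protein, per the labels. There were 2 biological replicates in 1 group, and the labels call them biological replicates without saying how the cultures were separated. No sample without the tagged protein and no input library was analysed here. The labels name a control for both replicates, whose kind is not given in the sources used here; a file from which the lists of both replicates derive is taken to be that control.

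The files are peak lists on the ce11 assembly, per the file names. 4 pairs of lists were used: 1 pair for each replicate alone, 1 pair from the pooled reads of both, and 1 pair that compares the 2 true replicates, told from the pooled pair by a file name and by the offsets of the summits within the peaks. Each pair has a ranked list and a shorter list that the authors thresholded on the irreproducible discovery rate (IDR, the expected share of irreproducible peaks). The signal of a peak is its value as deposited by the authors, and how it was scaled for sequencing depth is not given in the sources used here. In the pooled and true-replicate lists it is taken to be that of the peak in the pooled reads of both replicates. It therefore differs from the signals in the 2 compared lists. The score of a peak, as deposited by the authors, is a whole number computed from the IDR, and the −log10 of the IDR stands in a separate deposited column of the ranked lists. Peak caller, aligner and their versions are not given in the sources used here. Per the texts deposited with the lists, the lists of both replicates derive from 1 shared file besides their own alignments, and the thresholded lists used 1 further annotation file that the ranked lists did not use. The highest IDR among the peaks that the authors kept is 0.00997, so their threshold was taken as 0.01. The true-replicate ranked list also gives the signal of each peak in each of the 2 compared lists. The layout does not say which replicate is list 1 and which is list 2. Over the regions, the highest signal is 132.634 in list 1 and 87.7901 in list 2. These equal the highest signals of replicate 1 alone and of replicate 2 alone, so by value list 1 is replicate 1 and list 2 is replicate 2. Read counts are in none of these lists, so the depth per sample is unknown, and no interval that needs it is given. Intervals on shares of regions are 95% Wilson intervals and cover counting error over regions only. Where a count is 0, the limit given is 3 counts of the total, in place of a Wilson interval.

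The true-replicate thresholded list is the main list. Peaks that overlapped by at least 1 bp were merged into regions, each with the summit and signal of its strongest peak. Genes came from Ensembl release 115 for WBcel235, which is the same assembly as ce11, and sequence and small RNA products from RefSeq for that assembly; all peaks ended within the chromosome lengths of the reference. Coordinates are counted from 1. A summit from 1000 bp upstream to 250 bp downstream of the start of a protein-coding transcript counted as promoter. A summit within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene counted as a small RNA region. The comparisons other than those with small RNA genes, with tRNA gene copies, with peak rank and of base composition were fixed before the data were examined, as were the 23 lists of protein-coding genes; the small RNA rule, with its distance, was chosen after the data were seen.

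Shares were compared with 10000 draws of as many summits from lower-ranked peaks of the same list, matched on chromosome and overlapping no region (one-sided permutation test, smallest p 1e-04). Chromosome shares and gene lists used two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05, over 6 chromosomes and over 23 lists; the background for lists was the protein-coding genes with any ranked summit in the promoter window. GTCT, the core of the sequence that SMAD proteins bind, and its reverse complement AGAC were counted within 50 bp of each summit and in flanks 300 to 400 bp away, with a two-sided sign-flip permutation test of 100000 resamples over regions and 10000 bootstrap samples for the interval. Each 6-mer was compared between 100 bp either side of the summit and a flank 300 to 500 bp away with an exact McNemar test and Benjamini-Hochberg adjustment over 2080 6-mers. Regions are neighbours on 1 genome and not independent replicates, so p-values over regions describe these lists and not the spread between worms. The named regions are the 25 of highest signal, each with the nearest protein-coding start and a divergent gene within 1000 bp; members of the lists with a region in the promoter window are named as well, in full for the TGF-beta and dauer lists and up to 4 by signal for the others. A region named outside that rule is said to have been chosen after its values were seen.

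The tests were also run on simulated data. With nothing planted, 4.0% of 200 simulations of 217 summits passed for promoter share, 5.0% of 200 simulations at random genomic positions passed for GTCT density, 2.0% of 100 simulations gave any passing 6-mer among 2080, and 2.0% of 100 gave any passing gene list among 23. A promoter share of 40% was recovered in 99.5% of 200 simulations, and 7 planted ribosomal protein genes in 100% of 100. The real data also had 7 such genes with a region, so this recovery says nothing about smaller counts. A first form of the GTCT simulation used summits of lower-ranked peaks as its null. These summits are themselves denser in GTCT than their flanks, so that form was replaced by random positions. The 5.0% for GTCT thus holds for random positions and not for peak summits. For 6-mers, the simulations compared flanks of lower-ranked peaks with each other. The 2.0% thus does not cover a difference in base composition between summits and flanks. The excess in lower-ranked peaks is given with the result.

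Alternatives were the pooled list, each replicate alone, a stricter threshold, other promoter windows, other flanks, other overlap rules and other backgrounds. The stricter threshold planned at the start was 0.01, which proved to be the authors' own and moves nothing; 0.001 was added for that reason. Further alternatives added after the data were seen leave out the small RNA regions, change the distance that defines them, or use the strongest lower-ranked peaks as background. A background of lower-ranked peaks with a signal of at least 66.5, the lower quartile of the regions, was chosen first and could not be run, because only 14 such peaks exist and chromosome II has 0. The 2000 strongest lower-ranked peaks took its place; their median signal of 46.3 is below the 73.3 of the regions, so that background is not matched on signal. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.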

Results

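DAF-8 is a receptor-regulated SMAD protein of the TGF-beta pathway that controls entry into the dauer larva, a resting stage of C. elegans. Sites recovered through a green fluorescent protein tag on DAF-8 were mapped by ChIP-seq in whole fourth-stage larvae, in 2 biological replicates of 1 group. No sample without the tagged protein was analysed, so recovery that does not need that protein stays open for all regions. The list comparing the true replicates held 240 thresholded peaks out of 101032 ranked ones, which merged into 217 regions covering 74772 bp. The pooled list held 282 peaks in 259 regions. Replicate 1 alone gave 62 peaks in 57 regions and replicate 2 alone 77 peaks in 69 regions. Depth is unknown, since the lists hold no read counts, and the signals given below are the authors' values per peak.

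Regions lay mostly at genes for small noncoding RNAs and at promoters. The comparison with small RNA genes was chosen after the data were seen. Of the 217 regions, 86 had their summit within 200 bp of a tRNA, snRNA or snoRNA gene, a share of 39.6% (95% Wilson interval 33.4 to 46.3%), against a mean of 0.953% in draws of lower-ranked peaks (permutation p = 1e-04, the smallest 10000 draws can give). tRNA genes, which encode the adaptors of translation, accounted for 55 regions. snoRNA genes, whose products guide modification of ribosomal RNA, accounted for 24 regions, and snRNA genes, which encode RNA parts of the splicing machinery, for 8. A single region can lie near genes of more than 1 of these kinds. Each of these 3 kinds exceeded its draws with an adjusted p of 2.667e-04 over 8 kinds of gene, while no region lay at an annotated rRNA or miRNA gene, which allows a share of up to 1.38% of regions for each (3 counts of 217). The count for rRNA holds for the thresholded list alone: 1 peak that passed the IDR threshold and that the authors left out of that list lay at the rRNA gene rrn-4.2, with a signal of 131. Of 612 annotated tRNA genes, 61 had a region, or 9.97%. Against the 2000 strongest lower-ranked peaks the expected share was 10.3% rather than 0.953%, so the excess over background was 3.83-fold there and 41.6-fold in the main comparison.

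**Figure D1:**
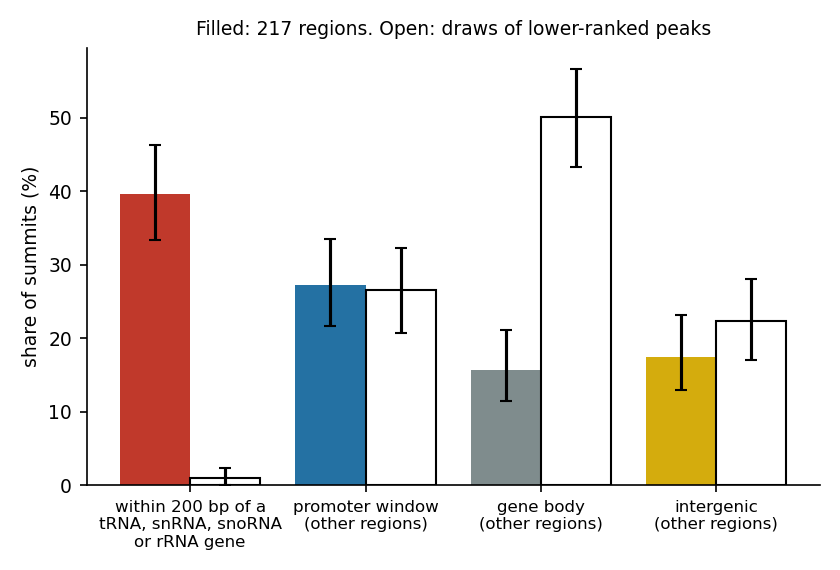
Share of summits (%) in each kind of place for the 217 regions (filled bars, 95% Wilson intervals) and for 10000 draws of lower-ranked peaks (open bars, mean with the central 95% of draws). Each region is counted once, in the leftmost class that applies, which lowers the shares of the classes to the right; small RNA regions make up 39.6% against 0.955% in these draws, and gene bodies 15.7% against 50.2%.

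Of the regions away from small RNA genes, 59 lay in promoter windows, 34 in gene bodies and 38 between genes. Some of these lay within 200 bp of genes that are neither protein-coding nor of the small RNA biotypes. Examples are mrpr-1, srpr-2.1 and srpr-1.2, named after their values were seen. They stay in the comparisons without small RNA regions. Without the small RNA regions, promoter windows held 45.04% of 131 regions against 26.99% in draws (permutation p = 1e-04). As shares of all 217 regions, with small RNA regions counted first, these promoter regions made up 27.2% against 26.6% (permutation p = 0.4418) and gene bodies 15.7% against 50.2% (permutation p for a lower share = 1e-04), and that order lowers both shares. Without it, 6.45% of summits lay in coding exons against 29.9% of lower-ranked peaks, and 31.8% in introns against 32.3%. Outside protein-coding genes, with promoter windows and small RNA genes there included, lay 57.6% against 33.4%. These values were not tested. The summits of the 55 tRNA regions centred on the gene, with a median of -13.5 bp from its middle along its strand and quartiles of -41 and 13.8 bp, and 39 of them were within 50 bp of the middle. No tRNA isotype differed from the rest after adjustment (adjusted p = 1 for each, Fisher's exact test). The share at small RNA genes was 40% in the first 50 peaks, 44% in peaks 51 to 100 and 35.7% in peaks 101 to 240. It was lower beyond the threshold, with 21.5% of peaks 241 to 500, 3.23% of peaks 2001 to 5000 and 0.459% of those beyond 50000.

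**Figure D2:**
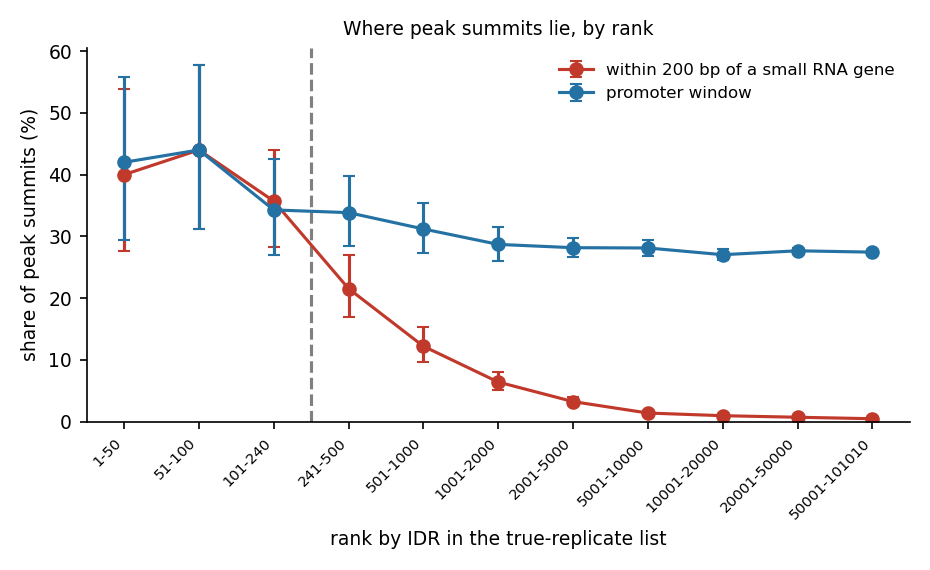
Share of peak summits (%) within 200 bp of a small RNA gene (red) and in promoter windows (blue) by rank of IDR in the true-replicate list, without the 22 peaks that the authors left out of the thresholded list, with 95% Wilson intervals; the dashed line marks the authors' threshold after rank 240. The small RNA share is between 35.7% and 44% up to rank 240 and 0.459% in the last group, and the promoter share is 42% in the first 50 peaks and 27.4% in the last group.

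The strongest regions came from the same kinds of place. Of the 25 with the highest signal, 8 were small RNA regions, 8 were promoter regions, 6 were intergenic and 3 were in gene bodies. Intergenic here means outside protein-coding genes, outside their promoter windows and not within 200 bp of a small RNA gene. The highest signal, 215, was an intergenic region on chromosome IV at 4725559 to 4725639, with 107 ± 35.7 (SD, n = 2) over the 2 compared lists. It lay 437 bp downstream of the start of K08F11.1 and within 200 bp of K08F11.7, a gene not annotated as protein-coding. A second intergenic region near K08F11.1, at 4727862 to 4728185, had a signal of 181. It lay within 200 bp of K08F11.6, also not annotated as protein-coding. The shared promoter of F44E5.5 and F44E5.4, divergent genes of the Hsp70 chaperone family, had 185 at II 11759339 to 11759662. The promoter of tasp-1 had 174 at III 10759113 to 10759436, with 87.4 ± 12.7 over both lists. A region in an intron of ints-8 on chromosome I, from 13463787 to 13464317, had 157 and lay within 200 bp of rpr-1, the RNA component of RNase P, which the 4 small RNA biotypes do not include.

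Small RNA regions among the strongest were the snoRNA genes ZK994.7 (V 8500431 to 8500754, signal 141), F55A11.10 (V 11782776 to 11783301, 139) and the pair C51F7.3 and C51F7.4 (V 12303472 to 12303795, 134), all in introns of protein-coding genes. The snoRNA gene T06C12.16 had 118. Neighbouring tRNA genes F15G9.t1 and F15G9.t2 (tRNA-Ala, X 9743514 to 9743837) had 136, M02F4.t1 and M02F4.t2 (X 3035976 to 3036299) had 126, and F22G12.t1 (tRNA-Val) had 111. The snRNA gene R07E5.16 had 113. Promoter regions among the strongest were those of pck-2, a phosphoenolpyruvate carboxykinase gene (I 7869073 to 7869396, signal 135), Y17G9B.5 with rpl-20 (IV 4749924 to 4750247, 122), the ribosomal protein gene rpl-3 (III 3867424 to 3867747, 118), tag-340 with nhl-2 (115), cdc-48.1, which encodes an AAA ATPase (II 10563406 to 10563729, 112), and mtcu-2 (111). The nearest starts to the remaining strong regions were those of zip-11 (signal 139), ccm-2 (136), cmd-1 (130), F40E3.3 (119.3), W02H3.3 (113) and zip-2, a bZIP gene (108). The region nearest to cmd-1 lay within 200 bp of linc-128, which is not protein-coding. Of these 25 regions, 24 passed the IDR threshold in the pooled list, 25 in replicate 2 alone and 18 in replicate 1 alone. The zip-2 region was the one that did not pass in the pooled list.

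Promoter windows held 84 of the 217 summits when small RNA regions were counted too, or 38.7%, against 26.8% in draws (permutation p = 3e-04). Genes for ribosomal proteins and chaperones stood out among the 23 lists. Ribosomal protein genes had a region in 7 of 77 members, or 9.09%, against 0.600% of other genes (odds ratio 16.6, adjusted p = 1.394e-05, two-sided Fisher's exact test). The strongest were rpl-20, rpl-3, rpl-35 (signal 90.6) and rps-19 (89.5). The count was 3 of 67 in replicate 2 alone (adjusted p = 0.0304) and 3 of 61 in replicate 1 alone (adjusted p = 0.0172, Fisher's exact test for each). Heat shock protein genes had a region in 4 of 44 (odds ratio 16.1, adjusted p = 0.00205, Fisher's exact test): hsp-90 (91.7), the endoplasmic reticulum chaperone gene hsp-3 (85.7), dnj-28 (74.6) and hsp-1 (67.3). That list was built from gene names, mostly hsp and dnj, and leaves out F44E5.5 and F44E5.4. The heat shock call was lost in each replicate alone, with 1 member and adjusted p = 0.639 in replicate 2 and 2 members and adjusted p = 0.0576 in replicate 1 by Fisher's exact test, and at an IDR of 0.001, where 1 member gave 0.488. Members of lists that did not pass included ins-39 (signal 83.3), his-37 (89.9), col-94 (61.8), the vitellogenin gene vit-6 (78.5), nhr-255 (87.4), sre-23 (88.98) and srh-269 (65.5); the regions of the last 3 also lay at small RNA genes. These belong to the lists of insulin-like peptides, histones, collagens, vitellogenins, nuclear hormone receptors and chemosensory receptors, of which the lowest adjusted p was 0.751 (Fisher's exact test). The lists of neuropeptides, Notch and distal tip cell, body wall muscle, pharynx, neurons, hypodermis, germline, homeobox, Rab and Arf GTPase, transcription machinery and splicing factor genes had 0 members with a region.

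No region lay in the promoter window of a member of the pathway lists. The DAF-7 TGF-beta list had 0 of 11 members with a region, the Sma/Mab BMP list 0 of 13, the dafachronic acid list 0 of 8 and the insulin signalling list 0 of 10, which allows shares of up to 27.3%, 23.1%, 37.5% and 30%. With 0.643% of other genes bound, counts of 0 were within what lists of this size give by chance (adjusted p = 1 for each, Fisher's exact test), so no depletion was detectable. Outside the promoter windows, 1 region had a member of these lists as its nearest gene: it lay in an intron at II 14040321 to 14040644, 2762 bp upstream of the start of daf-5, with a signal of 65.8, and is named after its values were seen. The strongest ranked peak at a promoter of these genes was that of egl-4, a cGMP-dependent protein kinase gene, with a signal of 54.01 and an IDR of 0.0461. It was followed by din-1 with 52.3 and an IDR of 0.0383. The promoter of daf-7, which encodes the ligand of the pathway, had 23.5 at an IDR of 0.684.

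The replicates shared sites more often than random members of their lists. Of the 62 peaks of replicate 1, 25 were overlapped by a peak of replicate 2, or 40.3% (95% Wilson interval 29.0 to 52.7%), against 0.158% in draws (permutation p = 1e-04). Of the 77 peaks of replicate 2, 26 were overlapped by replicate 1, or 33.8%. The lists of both replicates derive from 1 shared file, taken here to be the control. Over the 240 thresholded peaks Spearman's rho between the 2 lists was 0.0914 (permutation p = 0.161) and Pearson's r on the log scale 0.289 (permutation p = 1e-04), a correlation across sites, which are not independent replicates. These peaks were selected by an IDR computed from the same lists, which narrows the range of signals; over all 101032 ranked sites rho was 0.165 (permutation p = 0.001). The share of small RNA regions was 38.6% in replicate 1 and 40.6% in replicate 2 (Fisher's exact p = 0.856). The replicates share sites, which this test treats as independent, so it does not measure their agreement.

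**Figure D3:**
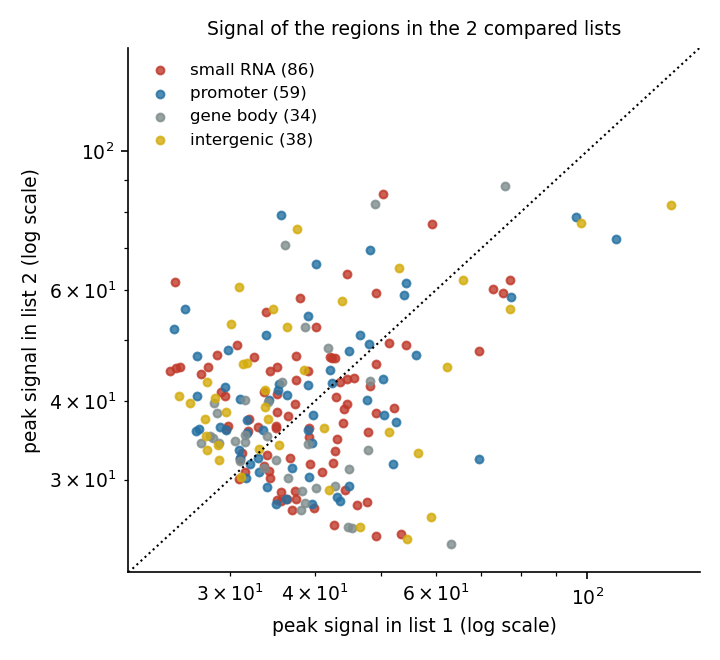
Peak signal of the 217 regions in list 1 and list 2 of the true-replicate comparison, both axes on a log scale, coloured by the place of the summit; the dotted line marks equal signal. The highest point on the list 1 axis is the region near K08F11.1, with 133 in list 1 and 82.1 in list 2.

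Chromosome X held more regions than the other chromosomes relative to lower-ranked peaks. It had 62 of 217 regions, or 28.6% (95% Wilson interval 22.97 to 34.9%), against 17.4% of lower-ranked peaks (odds ratio 1.89, adjusted p = 2.919e-04 over 6 chromosomes, Fisher's exact test). No other chromosome passed, with the lowest adjusted p of 0.153 on V. X also carries 276 of the 612 tRNA genes, or 45.1%. Without the small RNA regions, X held 22.1% of 131 regions against 17.3% (Fisher's exact test, p = 0.165). With the small RNA regions included, X held 23.9% against 17.7% in the pooled list (Fisher's exact test, p = 0.0112). It held 19.3% against 17.03% in replicate 1 alone (p = 0.599) and 33.3% against 17.4% in replicate 2 alone (p = 0.00122, Fisher's exact test for each). At an IDR of 0.001 it held 22.5% against 17.4% (Fisher's exact test, p = 0.403). These p-values and the one without small RNA regions are unadjusted.

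**Figure D4:**
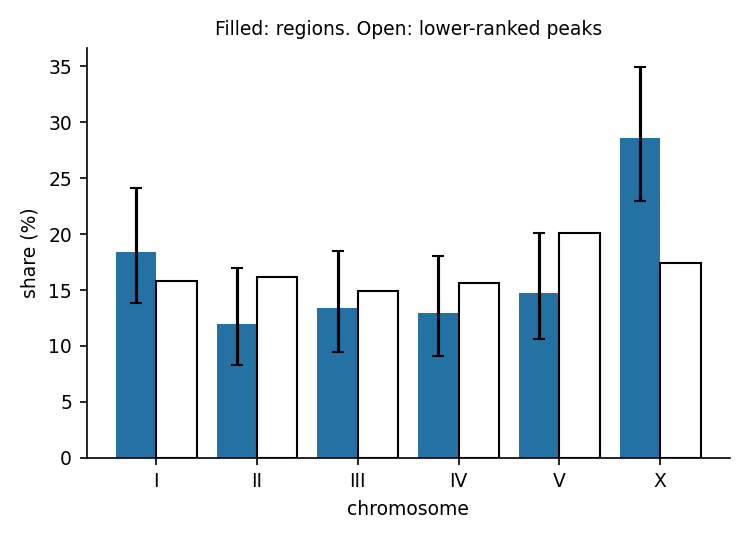
Share (%) of the 217 regions on each chromosome (filled bars, 95% Wilson intervals) and of lower-ranked peaks (open bars). X holds 28.6% of regions and 17.4% of lower-ranked peaks.

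GTCT was denser at summits than in the flanks of the same regions, with 0.798 against 0.497 per 100 bp, a difference of 0.301 (95% bootstrap interval 0.164 to 0.443, SD over regions 1.05, permutation p = 6e-05, higher at the summit in 98 regions and lower in 69). The same difference was 0.0442 over all lower-ranked peaks, which the regions exceeded by 0.257 (permutation p = 1e-04), and 0.138 in the 2000 strongest of them, which they exceeded by 0.163 (permutation p = 0.0127). It was 0.258 in the 500 strongest, and the test of the regions against those did not pass (difference 0.0427, permutation p = 0.4465). It was 0.193 in the 131 regions without small RNA genes (permutation p = 0.0505) and 0.222 in replicate 2 alone (permutation p = 0.120), and 0.186 at an IDR of 0.001 (permutation p = 0.261). Of 2080 6-mers, 293 passed, 178 denser at summits and 115 in flanks. CGAACC, with reverse complement GGTTCG, was in 57 summit windows and 7 flanks (exact McNemar test, adjusted p = 2.160e-08), and without small RNA regions in 14 and 3 (adjusted p = 0.131). GCGCGC was in 34 and 1, and without small RNA regions in 25 and 0 (exact McNemar test, adjusted p = 1.240e-04). Replicate 2 alone gave 16 passing 6-mers and replicate 1 alone gave 1, and at an IDR of 0.001 none passed. Summits held 49.7% ± 8.57 G and C (SD over 217 regions) against 38.7% ± 8.73 in lower-ranked peaks.

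The transgene carries daf-8 and unc-119 sequence, so the copy number of both loci can differ from that of the rest of the genome. Within 20 kb of daf-8 (I 8584424 to 8587507) there was 1 thresholded peak, at 8578058 to 8578381 with a signal of 62.3 and an IDR of 0.00812, and none in the pooled list or in either replicate alone. The thresholded peak lay 144 bp upstream of the start of rskn-1, in its promoter window. That gene is named after its values were seen. Ranked peaks within 20 kb of daf-8 had a median signal of 24.0, above that of 99.5% of 1000 random windows. In the other lists the medians there were closer to those of all ranked peaks, with 18.7 against 16.2 in the pooled list, 12.8 against 12.3 in replicate 1 and 13.2 against 12.7 in replicate 2. Within 20 kb of unc-119 (III 10902641 to 10908935) there was no thresholded peak, and the median of 18.2 was above that of 73.7% of random windows.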

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

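The look at peaks left out of the thresholded lists was chosen after the data were seen. The strongest peak of the true-replicate ranked list is not among the thresholded peaks. It lies between genes on X at 15810947 to 15811270, with a signal of 541, against 215 for the strongest peak kept, and it was singled out because it is signal outside the peaks that the comparisons use. In all, 22 peaks of that list pass the IDR threshold and were left out by the authors, 3 of them stronger than any kept peak, and 1 of them lies at a small RNA gene, the rRNA gene rrn-4.2. The lists derive from 1 further annotation file at this step; its content was not analysed here, and no explanation was tested.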

How the results depend on the processing

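The small RNA share with its alternatives was chosen after the data were seen. So were, for the other results, the alternatives at a threshold of 0.001, without small RNA regions or against lower-ranked peaks by signal. The comparison of GTCT with all lower-ranked peaks was not planned at the start either. Small RNA share and promoter share kept their direction and their side of the threshold under every alternative run, with small RNA shares from 34.6 to 40.6% and promoter shares from 24.0 to 56.7%; replicate overlap did so too, from 33.8 to 52.9%. The 0.01 threshold is the authors' own and tests nothing. A background of lower-ranked peaks of like signal could not be run, since only 14 exist, so it stays open how far these shares follow peak strength alone. The region count of 217 fell to between 57 and 69 in the replicates alone, where the cause was not tested, and to 40 at 0.001, where fewer peaks enter by construction. The correlation of signals passed its test over all ranked sites, at 0.165 (permutation p = 0.001), where 101032 sites enter. The X share was between 19.3 and 33.3% in the replicates alone, 22.5% at 0.001 and 22.1% without small RNA regions. It lost its call in replicate 1 alone, at 0.001 and without small RNA regions. In the pooled list it was 23.9% (Fisher's exact test, p = 0.0112). These alternatives were judged by unadjusted p-values, so whether the pooled call holds after adjustment over 6 chromosomes was not tested. The GTCT difference was between 0.222 and 0.304 in the replicates alone, lost in replicate 2 alone, and lost at 0.001 (0.186), without small RNA regions (0.193) and against the 500 strongest lower-ranked peaks (0.0427); it was kept against the 2000 strongest. Passing 6-mers numbered between 1 and 16 in the replicates alone, 0 at 0.001 (exact McNemar test, 112 at an unadjusted p under 0.05) and 111 without small RNA regions, from fewer regions each time. Passing gene lists numbered 1 in each replicate alone and 1 at 0.001, the ribosomal list each time. Of the 25 strongest regions, 7 missed the IDR threshold in replicate 1 alone. Fewer regions lower the power of each of these tests, and whether that alone ended the calls was not tested. Depth is unknown and limits no statement by number. No paired analysis was possible because there is 1 group.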

Other observations

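All tests in this part were chosen after the patterns they address were seen, and 4 of them were settled later still: the bound that decides the test on X and the use of small RNA genes without a region to judge binding at GTCT came after the values of those tests were seen, the criterion for single-base composition after the values of the single words, and the test on recovery without the tagged protein after the small RNA share. Regions outside the naming rule, also chosen after their values were seen, lay at sls-2.2, sls-2.8 and sls-2.9. The first, a gene for the spliced leader SL2, had a signal of 89.3 at II 5543430 to 5543753. The regions at sls-2.8 and sls-2.9 had signals of 68.8 and 60.3, and the latter also lay at a tRNA gene. tRNA genes counted as single-copy where their sequence equalled that of no other annotated tRNA gene. Single-copy genes had a region in 10 of 143, or 6.99%, and multi-copy ones in 51 of 469, or 10.9% (Fisher's exact p = 0.204).

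A first pattern is the share of small RNA genes among the regions. Reads shared between identical tRNA copies were predicted to leave single-copy genes at the level of draws. Of these genes, 6.99% had a region against 0.225% in 10000 draws, with 1.40% at the upper end of the central 95% of draws. A single-copy gene could still be nearly identical to another, or lie within 200 bp of a summit at a neighbouring copy. The test therefore cannot exclude shared reads, and it covers no snoRNA or snRNA gene. Binding at GTCT sites may contribute, since small RNA regions had an excess of 0.466 per 100 bp; but small RNA genes without a region had one of 0.234 (95% bootstrap interval 0.176 to 0.291) around their middle, and genes with a region exceeded them by 0.0872 (interval -0.112 to 0.295), so GTCT in the genes themselves and GTCT as a binding site cannot be told apart. Recovery that does not need the tagged protein, such as open and heavily transcribed chromatin precipitating with any antibody, is a candidate explanation for the 39.6%. It stays open, for the other regions too, because no sample without the tagged protein was analysed here. Binding at GTCT was the one biological explanation tested, and the design, with 1 group, names no other.

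A second pattern is the excess of GTCT at summits. Among 12 words made of the same bases, each with its reverse complement, GTCT came in place 1 by summit minus flank, with 0.301, and 9 of the 11 others lay below the lower limit of its interval (0.164 to 0.443). Single-base composition would raise these words alike, yet GTCT exceeded their mean of 0.0564 by 0.245 (95% bootstrap interval 0.104 to 0.390), so it does not account for the whole excess. Sequence of the summits beyond single bases stays open, since GTTC had 0.278, inside the interval of GTCT. GTTC is part of GGTTCG, the 6-mer with the lowest adjusted p. That 6-mer was in 57 summit windows over all regions and in 14 without small RNA regions. Whether the excess of GTTC comes from the small RNA regions was not tested. Peak strength stays open as well, given the 0.258 in the 500 strongest lower-ranked peaks.

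Another pattern is the excess on X. The positions of tRNA genes are a candidate source: without small RNA regions the share was 22.1%, with a 95% Wilson interval of 15.9 to 29.98% that holds both the 17.3% of lower-ranked peaks and the 28.6% of all regions. The test therefore leaves open whether an excess remains. Among tRNA genes alone, 13.0% of those on X and 7.44% of those on autosomes had a region (odds ratio 1.87, Fisher's exact p = 0.0294, unadjusted). Among the 86 small RNA regions, X held 38.4% against a background of 28.9% (Fisher's exact test, p = 0.0828, unadjusted).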
